A study of Mus musculus with 9 samples.

How the data were processed

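The arrays had been processed before they were deposited. Per the submitters' processing notes, probe values were normalised with RMA in Partek 6.6, and the version of RMA was not given. The deposited values were on a log2 scale, with a range of 1.10 to 14.1 over 41345 probe sets and 9 arrays, and were analysed without further transformation. Per the labels' protocols, NK cells were enriched with DX5 magnetic beads and expanded in IL-2 (split on days 4 and 6), RNA was extracted with TRIFAST and RNeasy, and Affymetrix WT PLUS chemistry was used for labelling.

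Probe sets were joined to genes through the platform annotation by probe set ID. Of the 41345 probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 were not listed. By Entrez ID, 23328 matched the RefSeq gene table (GRCm38.p6), and no symbol changed. The build that the authors used was not given, so this table served only for chromosomes and for the order of neighbouring genes. A probe set with 1 symbol was kept if it reached the median of its array on at least 3 of 9 arrays (13245 probe sets), and the brightest represented the gene where several passed (530 genes), which left 12579 genes.

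Genes were compared with limma (lmFit and eBayes, group means over all 9 arrays, prior degrees of freedom 2.407), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The labels state 3 independent experiments, and the same replicate number stands for the same experiment, so the samples are paired. Deviations from the genotype mean correlated, among pairs of arrays of different genotypes, at 0.383 to 0.787 when they shared an experiment and at -0.71 to 0.559 when they did not. The fit with the experiment as an additive block was therefore reported beside the unpaired fit. Values are log2 differences, genotype named first minus genotype named second, and SDs are over 3 arrays.

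Gene lists were written from general knowledge of NK cells: 26 lists with 579 distinct members, of which 520 had a probe set of their own and 430 were tested. The 22 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and were adjusted over the lists of a comparison. Camera compares a list with all other genes, whereas fry does not. Within a list, p-values were also adjusted over its members alone. The lists, the comparisons, the threshold, the rule for named genes and the alternatives were fixed before the data were examined, except where stated otherwise.

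The rule named Tyk2, key genes of NK cell and interferon biology and, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in all 3 experiments. Where fewer than 5 genes passed, the 10 smallest p-values were named too, and from each list up to 4 members with the smallest p.

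The alternatives were the experiment as a fixed or random block, only the 2 genotypes compared, no filter or a 70th percentile filter, median centring, quantile normalisation, an intensity trend in eBayes, array weights, the mean over probe sets of a gene, other thresholds, the 2 other list tests and leaving out each array or experiment. The same alternatives within the paired fit and the test of probe sets without a single gene name were added after the data were seen.

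The procedure was tested on simulated data with 12579 genes, in which 67, 67 and 66 genes were changed by log2 0.5, 1 and 2. The unpaired fit recovered 35.8%, 76.1% and 100% of them with 0 false calls, and the paired fit recovered 68.7%, 95.5% and 100% with 5 false calls. A simulated shift of -0.3 in the type I interferon-stimulated list was called (adjusted p = 1.6e-42) and 0 of the 21 other lists were. The simulated noise was independent between genes, so this cannot show how often lists of correlated genes are called falsely. The software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.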

Results

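Natural killer (NK) cells, innate lymphocytes that kill infected and transformed cells and release interferon-gamma, were enriched from the spleens of female C57BL/6N mice of 3 genotypes. Tyk2 encodes a Janus kinase that relays signals from the receptors for type I interferons, IL-12 and related cytokines. The mice were wild type (WT), deficient in Tyk2 (Tyk2-/-) or carried a kinase-inactive form of it (Tyk2K923E). Cells were pooled from 3 to 4 mice per genotype and experiment and were grown for 7 days in recombinant human IL-2 at 5000 U/ml. RNA of each genotype was hybridised in 3 independent experiments, 1 array per genotype and experiment, which gives 9 arrays. The medians over all 41345 probe sets lay between 5.42 and 5.48 log2 units. Across the 12579 genes tested, which are not independent replicates, the 36 pairs of arrays correlated at 0.966 to 0.997. With 3 arrays per genotype, the number of arrays limits the precision, and an exact test of 3 against 3 values cannot give a p below 0.1.

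The arrays of experiment 1 stood apart from those of experiments 2 and 3. The first principal component held 61.0% of the variance and separated the 3 arrays of experiment 1 from the other 6, whereas the second held 10.8% and placed each WT array above the Tyk2K923E array of its experiment. Arrays of different genotypes from the same experiment deviated together from their genotype means, with correlations of 0.383 to 0.787 in 9 pairs, so values from the fit with the experiments paired stand beside the unpaired ones where they change a call.

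**Figure D1:**
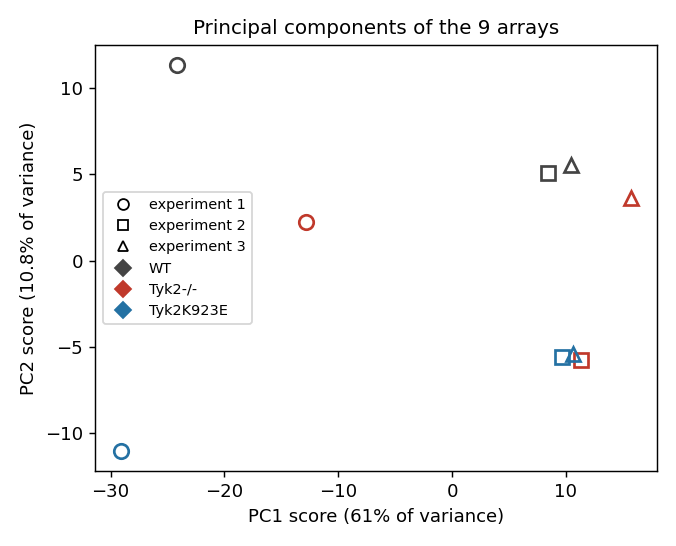
Scores of the 9 arrays on the first 2 principal components of 12579 genes, with the share of variance on each axis; colours mark genotypes and marker shapes mark experiments. The 3 arrays of experiment 1 lie at first-component scores of -29.1 to -12.9 and the other 6 at 8.42 to 15.7.

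The targeted gene was examined first. The probe set of Tyk2 (17524620, chromosome 9) was not lower on the arrays labelled Tyk2-/-: they read 9.55, 8.63 and 8.85, with a mean of 9.01 ± 0.48 (SD, n = 3), against 8.62 ± 0.06 in WT and 8.53 ± 0.10 in Tyk2K923E. The log2 difference of Tyk2 was 0.39 (SE 0.21, limma adjusted p = 1) between Tyk2-/- and WT and -0.10 between Tyk2K923E and WT. The sources used here give neither the deleted part of Tyk2 nor the positions of the probes, so this reading cannot check the genotype labels, and directions below refer to the arrays as labelled. The 25 measured genes that flank Tyk2 on chromosome 9 showed a median log2 difference of -0.01 in Tyk2-/- (camera adjusted p = 0.932) and -0.03 in Tyk2K923E (camera adjusted p = 0.253), where Cdc37 differed by -0.18 and Icam1 by -0.29 without passing the test.

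The comparison of Tyk2-/- with WT asks what the absence of Tyk2 does to the transcriptome of IL-2-cultured NK cells. Wdfy4, which encodes a WD repeat and FYVE domain protein needed for cross-presentation in dendritic cells, rose 5.37-fold, from 5.86 ± 0.22 to 8.29 ± 0.12 (SD, n = 3). Ckap4, a membrane protein of the endoplasmic reticulum, rose 4.40-fold, from 5.25 ± 0.18 to 7.39 ± 0.14. Its WT level lies under the array medians, so the rise may be understated, but no background was measured. Ifi27, an interferon-inducible gene, fell by 1.35 on the log2 scale, from 8.44 ± 0.21 to 7.10 ± 0.11. Mapk8, which encodes the stress kinase JNK1, fell by 1.11, from 7.62 ± 0.14 to 6.51 ± 0.15. These 4 of 12579 genes passed in limma, each in the same direction in all 3 experiments. The adjusted p was 4.01e-04 for Ckap4, 8.29e-04 for Wdfy4 and 0.0138 for both Ifi27 and Mapk8. At an unadjusted p under 0.05 there were 262 genes unpaired and 1142 with the experiments paired, where 0.05 of all genes tested is 629. The unpaired fit counts differences between experiments as noise, so a count under 629 does not mean that no gene changed.

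With the experiments paired, 11 genes passed, 3 higher and 8 lower. Among those that missed the threshold unpaired, Casp4, an inflammatory caspase that responds to bacterial lipopolysaccharide in the cytosol, fell by 1.99 (adjusted p = 0.18 unpaired and 0.0353 paired). Itga1, the integrin chain CD49a, fell by 0.60 (adjusted p = 0.0571 and 0.0345), Ifi214, an interferon-activated gene, by 1.24 (0.519 and 0.0353) and Rtp4, an interferon-stimulated chaperone, by 1.11 (0.434 and 0.0446). Btg2 (-0.50), Slfn2 (-0.64) and Plxnb2 (0.53) also passed only with pairing, each at an adjusted p of 0.0446, and were chosen after their values were seen. Btg2 differed by -0.16 without WT replicate 1 and by -0.79 without Tyk2-/- replicate 1. Usp18, a brake on type I interferon signalling, differed by -1.26 (adjusted p = 0.736 and 0.0915) and Pisd-ps3 by 0.39, and both missed the threshold in either fit. Wdfy4 and Ckap4 stayed past the threshold when any 1 array of these genotypes was left out of the unpaired fit. Ifi27 and Mapk8 did not: without Tyk2-/- replicate 1, 2 or 3 their adjusted p was 0.0589, 0.14 and 0.143 for Ifi27 and 0.0589, 0.0849 and 0.0634 for Mapk8, without WT replicate 1 or 2 it was 0.0849 and 0.115 for Ifi27, and without WT replicate 2 or 3 it was 0.0859 and 0.055 for Mapk8. Usp18 passed without WT replicate 1 (adjusted p = 0.00675).

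**Figure D2:**
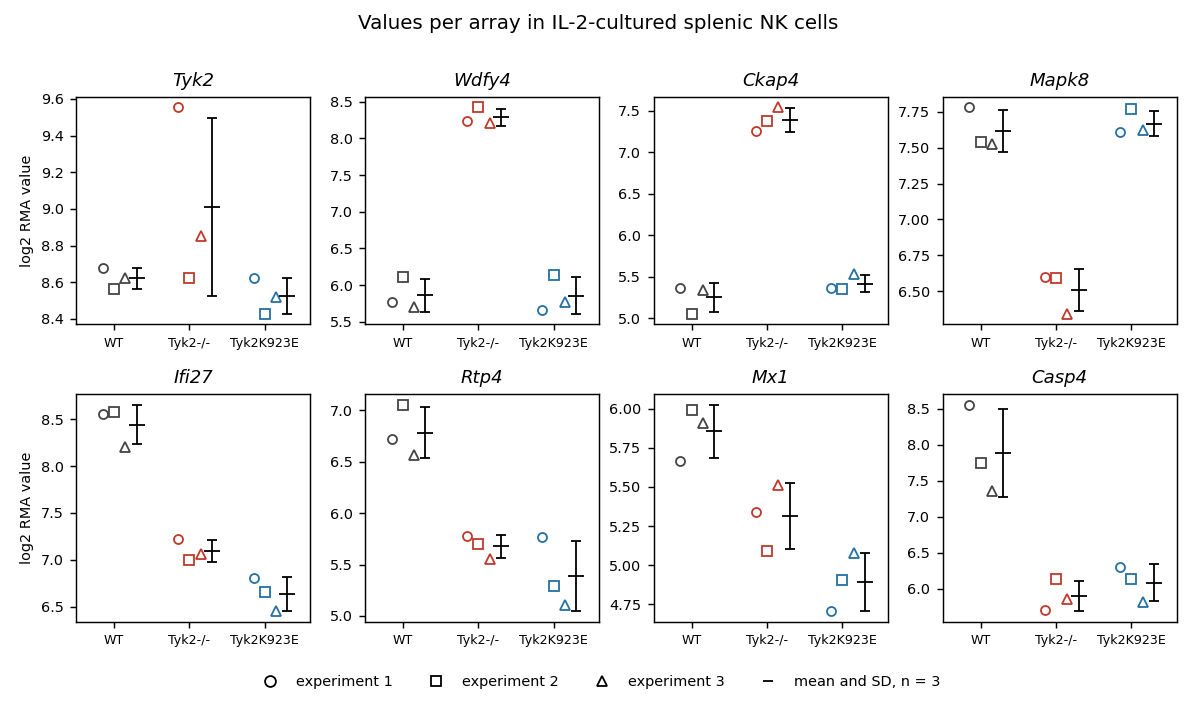
Deposited log2 RMA values of 8 genes on each of the 9 arrays; marker shapes give the experiment, and the bars give the mean and SD of 3 arrays per genotype. Wdfy4 and Ckap4 were high and Mapk8 low on the Tyk2-/- arrays alone, whereas Ifi27, Rtp4, Mx1 and Casp4 lay below WT on every array of both mutants; Tyk2 read 9.55 on 1 Tyk2-/- array and at most 8.85 on the other 8.

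Type I interferon-stimulated genes fell in Tyk2-/- cells as a group. Of 31 measured members, 30 were lower, with a median log2 difference of -0.29 (camera adjusted p = 1.14e-19, and adjusted p = 0.00642 with an estimated correlation). No member passed over all genes in limma and 11 had an unadjusted p under 0.05, whereas 8 fell when adjusted over the list alone (15 with pairing), among them Rtp4, Usp18, Oasl1 (-0.74) and the antiviral GTPase Mx1 (-0.54, or -0.36 without experiment 2). Irf7 and Isg15, key genes of the same response, differed by -0.33 and -0.37 and did not pass, except that Irf7 fell by the list alone with pairing (-0.21 without WT replicate 1). Isg15 ranged from -0.57 without experiment 2 to -0.09 without Tyk2-/- replicate 3. Its level of 5.31 in Tyk2-/- lay under the array medians, so its fall may be understated. NK cell surface receptors fell too: 25 of 28 were lower, with a median of -0.24 (camera adjusted p = 2.48e-13, and adjusted p = 0.0179 with an estimated correlation). Its members Klra9 (-0.92) and Klri2 (-0.58), both lectin-like receptors, and Klrk1 (-0.32), which encodes the activating receptor NKG2D, were not past the threshold singly, since 0 members passed over all genes or when adjusted over the list alone and 6 had an unadjusted p under 0.05. With the experiments paired, 10 receptors fell by the list alone, these 3 among them. These are 2 of the 11 lists called among 22 tested, and the call of each of the other 9 was lost with an estimated correlation.

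Interferon-gamma-inducible GTPases and antigen presentation genes were lower in 21 of 24 members, with a median of -0.09 (camera adjusted p = 3.02e-05, and adjusted p = 0.113 with an estimated correlation). Irgm1 differed by -0.28 and H2-K1 by -0.27, and with pairing both were among 3 members that fell by the list alone, against 0 unpaired. Chemotaxis and adhesion receptors had a median of -0.04 over 24 members (camera adjusted p = 0.00385, and adjusted p = 0.113 with an estimated correlation), and 4 fell when adjusted over the list alone: Itga1, Itgax (-0.88), Itga2 (-0.39) and Ccr2 (-0.29), or 6 with pairing. Itga2 encodes CD49b, the antigen of the DX5 antibody used to enrich the cells. Group 1 innate lymphoid cell-associated genes (11 members, median -0.12, with Cxcr6 at -0.72) and exhaustion and checkpoint receptors (11 members, median -0.15) gave camera adjusted p of 0.0065 and 0.00385, and adjusted p = 0.22 each with an estimated correlation. With pairing, 2 and 3 members fell by the list alone, against 1 and 0. Genes higher in mature NK cells (19 members, median -0.10, with Itgam at -1.18, or -0.76 without WT replicate 1 and -1.79 without Tyk2-/- replicate 1) and in immature NK cells (17 members, median -0.16) gave 0.0147 and 0.0206, and adjusted p = 0.113 and 0.282 with an estimated correlation. Of these, 4 and 5 members fell by the list alone with pairing and 0 without. The integrated stress response was higher, with a median of 0.07 over 21 members and Mthfd2 at 0.26 (camera adjusted p = 0.00668, or 0.08 with pairing, and adjusted p = 0.113 with an estimated correlation). Cell cycle genes were higher in 37 of 38 members, with a median of 0.13 (camera adjusted p = 0.0206, and adjusted p = 0.872 with an estimated correlation), but their mean turned to -0.07 without WT replicate 1 (camera adjusted p = 0.334).

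Cytotoxic granule and death ligand genes gave no call in Tyk2-/- cells unpaired (24 members, median -0.02, camera adjusted p = 0.0954) and were called lower with pairing (0.0435, and adjusted p = 0.366 with an estimated correlation). Gzmb and Prf1, granzyme B and perforin, differed from WT by 0.03 and 0.09, Gzma by -0.21 and Fasl by -0.21. Cytokines and chemokines made by NK cells gave none either (15 members, median -0.04, camera adjusted p = 0.0954), although the chemokine Ccl5 fell by 1.05 when adjusted over the list alone. With pairing 3 fell, Ccl5 and Ifng among them, and 2 rose, Lta among them. Ifng differed by -0.31, Lta by 0.34, Stat4 by -0.22, Il12rb2 by -0.04, Klrg1 by -0.10 and Il2ra by 0.33, and none of these passed over all genes. The remaining lists of NK cell functions, namely cytokine receptors and JAK-STAT components, IL-2 and STAT5 target genes, the respiratory chain, glycolysis and immediate early genes, had medians of -0.04 to 0.04 and camera adjusted p of 0.0509 to 0.932. Immediate early genes were called lower with pairing (0.0106, and adjusted p = 0.264 with an estimated correlation). Markers of T cells, which splenic NK cultures can hold, were lower in 12 of 13 measured members, with a median of -0.09 (camera adjusted p = 0.0101, and adjusted p = 0.401 with an estimated correlation) and with Cd8a at -0.32. The mean of this list ranged from -0.21 to -0.01 over the alternatives, and its call was lost in 8 of 20. The monocyte, dendritic cell and stromal lists gave camera adjusted p of 0.932 each, and the 4 other lists of foreign cells had fewer than 5 measured members and were not tested (medians 0.01 for B cells, -0.21 for neutrophils, -0.02 for basophils and mast cells and 0.05 for erythroid cells and platelets). Of these, the neutrophil list had Mmp9 lower by the list alone, from 5.90 to a level of 5.41 at the array medians, and the basophil marker Mcpt8 differed by 0.49 (0.24 without Tyk2-/- replicate 2) and rose by the list alone with pairing.

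**Figure D3:**
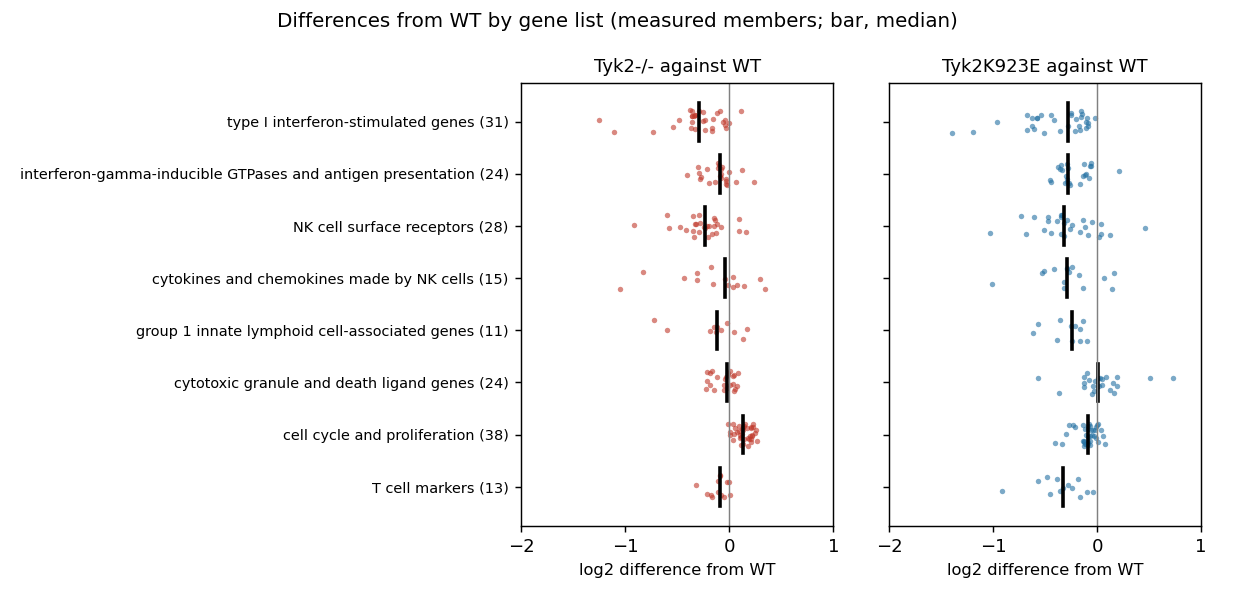
Log2 differences from WT of the measured members of 8 gene lists, with Tyk2-/- on the left and Tyk2K923E on the right; each point is a gene, bars are medians and the number of measured members follows each name. Type I interferon-stimulated genes lie below 0 in 30 of 31 members in Tyk2-/- and in 31 of 31 in Tyk2K923E, whereas the cytotoxic list is centred near 0 in both.

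The comparison of Tyk2K923E with WT asks what changes when the kinase is present but inactive. Ifi27 fell by 1.80 on the log2 scale, a 3.49-fold difference, from 8.44 ± 0.21 to 6.64 ± 0.18 (SD, n = 3; limma adjusted p = 0.00537). It was the only 1 of 12579 genes to pass, and it was lower in all 3 experiments. At an unadjusted p under 0.05 there were 529 genes unpaired and 1258 with the experiments paired, where 0.05 of all genes tested is 629. The same limit applies to the unpaired count. The call of Ifi27 was lost without WT replicate 2 (adjusted p = 0.0557) or without Tyk2K923E replicate 2 (adjusted p = 0.0675), with log2 differences of -1.74 and -1.81.

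With the experiments paired, 11 genes passed, 3 higher and 8 lower. Rtp4 fell by 1.40, Mx1 by 0.96, Ifi214 by 1.15 and Lgals3bp, a secreted glycoprotein of the interferon-stimulated list, by 0.63, each at a paired adjusted p of 0.0375 and an unpaired one of 0.155 to 0.379. In Tyk2K923E Rtp4 (5.38), Mx1 (4.90) and Ifi214 (4.65) lay under the array medians, so these falls may be understated. The same holds for Ifi214 (4.56), Mx1 (5.32) and Oasl1 (5.30) in Tyk2-/- and for the rise of Cfap300 from 5.31 in WT. No background was measured, so this was not tested. Casp4 fell by 1.80 (adjusted p = 0.244 unpaired and 0.0462 paired). The receptor Cd160 fell by 0.68 and the integrin chain Itga2 by 0.71 (adjusted p = 0.155 and 0.0375 for both). Myrf, a transcription factor, rose by 0.54 (0.234 and 0.0375). Mid1 on chromosome X (1.52) and Cfap300 on chromosome 9 (1.01) also rose with pairing, at an adjusted p of 0.0375, and were chosen after their values were seen. In Tyk2-/- the difference of Cfap300 from WT was 0.93 and missed the threshold in both fits (paired adjusted p = 0.0531). In the unpaired fit Rtp4 passed without Tyk2K923E replicate 1 (adjusted p = 0.0491). Gas2l2 (0.53), Phf11b (-0.67) and Ms4a6b (-0.69) missed the threshold in both fits.

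Type I interferon-stimulated genes fell in Tyk2K923E cells as well: 31 of 31 were lower, with a median of -0.28 (camera adjusted p = 3.83e-25, and adjusted p = 0.00321 with an estimated correlation). In limma 0 members passed over all genes and 13 had an unadjusted p under 0.05, whereas 12 fell when adjusted over the list alone (21 with pairing). Irf7 and Isg15 differed by -0.41 and -0.25, and Isg15 ranged from -0.48 without Tyk2K923E replicate 1 to -0.07 without WT replicate 1. At 5.43 in Tyk2K923E, Isg15 lay near the array medians, so its fall may be understated. Beside these groups, the T cell markers were lower in 13 of 13 members, with a median of -0.33 (camera adjusted p = 1.66e-08, and adjusted p = 0.0716 with an estimated correlation). Cd8a fell by 0.92 when adjusted over the list alone, Lat differed by -0.48 and Cd8b1 by -0.57, and these 3 fell by the list alone with pairing.

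Interferon-gamma-inducible GTPases and antigen presentation genes fell, with 23 of 24 lower and a median of -0.28 (camera adjusted p = 2.1e-13, and adjusted p = 0.0121 with an estimated correlation). None passed over all genes, 10 had an unadjusted p under 0.05 and 6 fell when adjusted over the list alone (12 with pairing), among them the immunity-related GTPases Igtp (-0.45) and Irgm1 (-0.34), the guanylate-binding protein Gbp4 (-0.28) and the transcription factor Irf1 (-0.29). NK cell surface receptors fell, with 23 of 28 lower and a median of -0.32 (camera adjusted p = 2.1e-13, and adjusted p = 0.0121 with an estimated correlation). No receptor passed over all genes unpaired, 9 had an unadjusted p under 0.05 and 6 fell when adjusted over the list alone (13 with pairing), among them Cd160, Klrk1 (-0.47), Klrc3 (-1.03, or -0.63 without experiment 2) and Klra6 (-0.74). Cytokines and chemokines made by NK cells fell, with 12 of 15 lower and a median of -0.29 (camera adjusted p = 5.95e-06, and adjusted p = 0.0121 with an estimated correlation), where Ccl5 fell by 1.01 when adjusted over the list alone and Tnf differed by -0.29. In this list 0 members passed over all genes and 7 had an unadjusted p under 0.05, and 8 fell by the list alone with pairing, Ccl5 and Tnf among them. With the experiments paired, the adjusted p with an estimated correlation was 0.0825 for the interferon-gamma list, 0.0506 for receptors and 0.0506 for cytokines, so that type I interferon-stimulated genes alone kept the call there, at 0.0124.

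Group 1 innate lymphoid cell-associated genes fell in Tyk2K923E cells, with 11 of 11 lower and a median of -0.24 (camera adjusted p = 2.46e-07, and adjusted p = 0.0335 with an estimated correlation), among them Itga1 (-0.39) and the death ligand Tnfsf10 (-0.57) by the list alone and Cxcr6 at -0.62, which joined them with pairing. Chemotaxis and adhesion receptors had a median of -0.08 over 24 members (camera adjusted p = 9.82e-05, and adjusted p = 0.0393 with an estimated correlation), and Itga1, Itga2 and Itgax (-0.68) fell when adjusted over the list alone, or 9 members with pairing. The integrated stress response rose, with a median of 0.10 over 21 members and Mthfd2 at 0.20 (camera adjusted p = 9.15e-04, and adjusted p = 0.0335 with an estimated correlation). With pairing, the adjusted p of these 3 lists with an estimated correlation was 0.113, 0.113 and 0.151. Cytokine receptors and JAK-STAT components had a median of -0.10 over 30 members (camera adjusted p = 2.96e-05, and adjusted p = 0.156 with an estimated correlation), with Stat4 at -0.44, Il10rb at -0.36 and Il18rap at -0.29, and 4 members fell by the list alone with pairing. Genes higher in immature NK cells had a median of -0.10 over 17 members (camera adjusted p = 0.00606, and adjusted p = 0.189 with an estimated correlation), and 5 fell by the list alone with pairing, against 0.

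Cytotoxic granule and death ligand genes gave no call (24 members, median 0.01, camera adjusted p = 0.395), although the granzyme inhibitor Serpinb9b rose by 0.51 and Tnfsf10 fell by 0.57 when adjusted over the list alone. Gzmb differed by 0.02, Prf1 by 0.19 and Ctsw by -0.36. Ifng differed by -0.17, Il12rb2 by -0.18 and Klrg1 by 0.30, and none passed. Cell cycle genes (median -0.09), the respiratory chain (0.04), glycolysis (0.01), IL-2 and STAT5 target genes (-0.05, with Socs1 at -0.27), immediate early genes (0.03, where Nr4a2 rose by 0.47 by the list alone), genes higher in mature NK cells (-0.01) and checkpoint receptors (-0.08) gave camera adjusted p of 0.12 to 0.404. Cell cycle genes were called lower with pairing (0.00499, and adjusted p = 0.701 with an estimated correlation). The mean of this list against WT was -0.39 in experiment 1, 0.11 in experiment 2 and -0.01 in experiment 3, so the fall came mainly from experiment 1. The monocyte, dendritic cell and stromal lists gave 0.829, 0.516 and 0.0591. Among 3 measured basophil and mast cell markers, Cpa3 was higher by 0.91 and Mcpt8 by 0.77, both at an adjusted p of 0.0168 over the list alone. Over all genes neither passed in limma (adjusted p = 0.857 for both), nor under any of the alternatives. With so few measured members, the list itself was not tested. The remaining member Cma1 read 8.23 in WT and 8.17 in Tyk2K923E. Only 3 of the 13 list members with a probe set of their own were above the filter. The neutrophil marker Mmp9 was lower by the list alone, at a level of 5.36 under the array medians.

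The direct comparison of Tyk2-/- with Tyk2K923E asks what differs between absence of the protein and loss of its kinase activity. Wdfy4 was 5.40-fold higher in Tyk2-/- than in Tyk2K923E (log2 difference 2.43, SE 0.15) and Ckap4 3.94-fold higher (1.98, SE 0.11). Mapk8 was 2.23-fold lower (-1.16, SE 0.10). In Tyk2K923E these genes lay at 5.86 ± 0.25, 5.42 ± 0.10 and 7.67 ± 0.09 (SD, n = 3). They were the 3 of 12579 genes that passed in limma (adjusted p = 8.11e-04, 7.66e-04 and 0.00962) and the 3 that passed with pairing, and each had the same sign in all 3 experiments. At an unadjusted p under 0.05 there were 303 genes unpaired and 1218 with the experiments paired, where 0.05 of all genes tested is 629. The same limit applies to the unpaired count. Ifi27, lower than WT in both mutants, differed between them by 0.46 (adjusted p = 1). The smallest p-values that missed belonged to Prkce (0.48, adjusted p = 0.209), Serpinb9b (-0.63), Mapk11 (0.74), Mettl6 (-0.35), Cd160 (0.44), Lta (0.66) and AI504432 (0.35). Mapk8 lost its call in 4 of the 6 sets with 1 array left out: without Tyk2-/- replicate 1 or 2 its adjusted p was 0.0514 and 0.0628, and without Tyk2K923E replicate 2 or 3 it was 0.0892 and 0.0793.

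Camera called 9 of 22 lists between the mutants, and none of these calls held with an estimated correlation. Type I interferon-stimulated genes were higher in Tyk2-/- than in Tyk2K923E by a median of 0.08 (camera adjusted p = 0.00589, and adjusted p = 0.307 with an estimated correlation). Interferon-gamma-inducible genes were higher by a median of 0.09, with Igtp at 0.43 (8.38e-04, and adjusted p = 0.307 with an estimated correlation), and cytokines by 0.15 (0.00919, and adjusted p = 0.307 with an estimated correlation), where Lta was the 1 member higher when adjusted over the list alone, Tnf differed by 0.32 and 3 members, both of these included, were higher with pairing. Cytokine receptors and JAK-STAT components were higher by 0.07 (0.00589), T cell markers by 0.27 (0.00112, with Cd8a at 0.60), cytotoxic genes lower by a median of -0.08 (0.0268, where Serpinb9b passed by the list alone), immediate early genes by -0.08 (0.00942, with Nr4a2 at -0.34) and stromal markers by -0.11 (0.0389, or 0.0568 with pairing), each with an adjusted p = 0.424 with an estimated correlation. Over the alternatives the mean of the immediate early list ranged from -0.16 to 7.8e-04, and its call was lost in 9 of 20. Cell cycle genes were higher in 37 of 38 members, with a median of 0.23 and Ccnb2 at 0.32 (5.75e-04, and adjusted p = 0.697 with an estimated correlation). Their mean turned to -0.13 without Tyk2K923E replicate 1 (camera adjusted p = 0.0185). The 13 other tested lists, among them NK cell surface receptors with a median of 0.02, gave no call, with camera adjusted p of 0.0543 to 0.825. Among lists without a call, median, mean and test differed in sign for the flanking, IL-2 and STAT5, monocyte, dendritic cell and stromal lists in Tyk2-/- against WT, for the dendritic cell list in Tyk2K923E against WT, and for the respiratory chain, glycolysis, chemotaxis and flanking lists between the mutants. The key genes Gzmb (0.01), Prf1 (-0.10), Ifng (-0.13), Stat4 (0.21), Il12rb2 (0.14), Klrg1 (-0.40), Irf7 (0.08) and Isg15 (-0.12) did not pass, nor did Socs1 (0.27), Tnfsf10 (0.38), Itga2 (0.32) and Cpa3 (-0.93), of which Cpa3 was lower by its list alone. Over the alternatives Stat4 ranged from 0.09 to 0.33, Il12rb2 from 0.04 to 0.21, Ifng from -0.22 to -0.03 and Tnfsf10 from 0.21 to 0.48.

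Genes that differed from WT in the same direction in both mutants were counted against chance. Ifi27 was the 1 gene called in both, where independent lists of these sizes would share 1.59e-04 genes. With the experiments paired, Ifi27, Rtp4, Ifi214 and Casp4 were called lower in both, where independent lists would share 0.00509, and 0 genes were called higher in both. In 100 simulations of unchanged genotypes that shared 3 simulated WT arrays, no gene was called in both. With no gene changed, few calls can arise in either genotype, so this cannot gauge how many shared calls the common WT arrays produce. Across genes, which are not independent replicates, the log2 differences of the mutants correlated at 0.516, against 0.499 (0.469 to 0.533) simulated from shared WT arrays alone. Their covariance was 0.00933 against 0.00502 (0.00459 to 0.0056), and the share with the same sign was 65.0% against 66.8% (65.8 to 67.9). The simulated noise was independent between genes, so these ranges are likely too narrow for genes that vary together. They cannot tell whether the observed values lie outside what shared WT arrays give. The 3 WT arrays cannot be split into sets of 2, so part of the excess of shared calls may come from the shared controls.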

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

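The tests of gene distance, of a chromosome segment, of Casp4 within experiments, of T cell markers and of leaving out experiment 1, and the analysis of probe sets without a single gene name, were chosen after the results were seen. The splits of the arrays were chosen before. The window around Wdfy4 and Mapk8 was placed on genes singled out by their calls, so its position was set after the results were seen.

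The effects of the mutants against the shared WT arrays differed, by a test of the difference itself, for 3 genes. The effect of Tyk2-/- minus that of Tyk2K923E was 2.43 for Wdfy4, 1.98 for Ckap4 and -1.16 for Mapk8 on the log2 scale.

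Probe sets that the annotation does not list, or lists with several genes, held larger differences than any named gene. Of 8283 tested, 2 rose in Tyk2-/- against WT and 197 had an unadjusted p under 0.05. Probe set 17549062 was higher by 5.67 and 17549150 by 6.03 (adjusted p = 6.59e-07 and 3.2e-07), from 5.80 and 6.24 in WT to 11.5 and 12.3 in Tyk2-/-, while Tyk2K923E read 5.57 and 6.11. In Tyk2K923E 3 fell against WT and 271 had an unadjusted p under 0.05. All 3, among them 17548738 and 17548740, had identical values, so they count as 1 measurement, which fell by 3.15. The limma adjusted p of 0.0412 (0.00815 with pairing) counted them as 3 tests. Counted as 1 test, the measurement would no longer pass the threshold unpaired. What these probe sets measure was not given, and no explanation was tested.

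Wdfy4 and Mapk8, which moved in opposite directions in Tyk2-/- alone, lie on chromosome 14, 3 places apart in the order of protein-coding genes (GRCm38.p6). Random sets of 3 tested genes held a pair as close in a share of 9.1e-04, but the distance was taken from the pair itself after it had been seen, so coincidence stays open. A change of the whole region is argued against by the 18 other tested genes within 20 genes on either side: their median size of change lay at percentile 23.7 of such windows. Another candidate explanation that stays open is a local difference in the DNA of the Tyk2-/- line that reaches both genes, which expression values cannot test. Ckap4 lies on chromosome 10, and neither the history of the alleles nor a genotype effect of Tyk2 itself was tested against this.

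Casp4 was lower and Cfap300 higher in both mutants, although the rise of Cfap300 in Tyk2-/- (0.93) missed the threshold unpaired (adjusted p = 1) and paired (0.0531), and both lie on chromosome 9, as Tyk2 does, 123 and 103 genes from it. Some laboratory strains carry a defective Casp4 allele, so a segment of another strain carried along with the Tyk2 alleles may contribute. The share of the segment's 127 other tested genes that changed alike in both mutants was at percentile 58.4 of equally long windows, which leaves this open; Casp1 in that segment, chosen after its values were seen, differed by -0.65 in both mutants and missed the threshold unpaired and paired. The bound first set would have excluded it, but was replaced after the result was seen, because a carried segment can differ at few expressed genes. That Casp4 is part of the lower interferon-stimulated expression stays open too: it was higher in 0 of 6 comparisons within experiments, which restates the fall that singled it out.

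Type I interferon-stimulated genes were lower in both mutants, with list means per experiment of -0.26, -0.37 and -0.30 in Tyk2-/- and of -0.40, -0.41 and -0.42 in Tyk2K923E. Fewer T cells could lower the list: the T cell list had means of -0.17, -0.01 and -0.15 in Tyk2-/- and of -0.52, -0.01 and -0.51 in Tyk2K923E, and lay above the interferon list by a mean of 0.20 (SD 0.14) and 0.0637 (SD 0.30), so in experiment 2 the interferon list was lower in both mutants while the T cell list hardly differed. This stays open in both mutants, because the markers have a high baseline (a median level of 7.91 over 16 markers and 11.35 for Cd3e in WT) that NK cells may share and that would hide a small change, and DX5 beads would not remove NKT cells. Without experiment 1 the larger camera adjusted p was 2.19e-16, which argues against that experiment as the source, although with an estimated correlation the adjusted p was then 0.197 in Tyk2-/- and 0.172 in Tyk2K923E. Loss of Tyk2 signalling is the explanation that the design names, and it remains a hypothesis.

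The 6 arrays of a comparison make 10 splits of 3 against 3, too few for a share under 0.05. In each comparison the real split was the only 1 of 10 to reach its count of genes and its count of lists. The real counts of genes were 4 for Tyk2-/- against WT, 1 for Tyk2K923E against WT and 3 for Tyk2-/- against Tyk2K923E, with 0 as the highest of the other splits each time. The real counts of lists were 11, 10 and 9, with 7, 8 and 6 as the highest others. Of the 4 splits that part all pairs, with the experiments paired, the real ones gave 11, 11 and 3 genes and the others at most 0.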

How the results depend on the processing

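The paired versions of each alternative were chosen after the data were seen. With 3 arrays per genotype the spread between experiments limits precision, and dim genes may lie near the background of the arrays, which was not measured. Of the alternatives to the log2 differences of named genes, 20 reversed a sign, 52 brought a gene past the threshold, 41 took one out and 2234 kept both sign and side. The Tyk2 difference kept its direction throughout (0.12 to 0.58 in Tyk2-/- and -0.15 to -0.05 in Tyk2K923E against WT). The type I interferon-stimulated and receptor lists kept their calls against WT when 1 choice at a time was changed, with highest adjusted p of 0.00938 and 0.0444 in Tyk2-/- and 0.00321 and 0.0121 in Tyk2K923E. With pairing and an estimated correlation together the receptor list lost its call in Tyk2K923E (0.0506), and without experiment 1 and with an estimated correlation the type I interferon-stimulated list lost its calls (0.197 in Tyk2-/- and 0.172 in Tyk2K923E), with 6 arrays in the fit and medians of -0.31 and -0.30 against -0.29 and -0.28 in the full set. Camera cannot take a random block, so that alternative was not run for lists. Where no cause follows from fewer arrays or a looser threshold, the cause was not tested.

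For Tyk2-/- against WT, 4 genes became 11 with a fixed block, 8 with a random block, 2 with only the 2 genotypes compared, 9 with array weights and 26 at an unadjusted p under 0.05 and at least 1.5-fold, and 0 to 4 with an array or experiment left out. For Tyk2K923E against WT, 1 gene became 11, 9, 0, 28 and 57 in the same order, and 0 to 2. For Tyk2-/- against Tyk2K923E, 3 genes became 17 at the unadjusted threshold and 0 to 3 with leave-outs. Genes called in both mutants went from 1 to 4 with either block, 6 with array weights and 0 to 1 with leave-outs. Array weights rest on few arrays per group, and the block takes out the difference between experiments.

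With the experiments paired, the 11 genes of Tyk2-/- against WT became 6 with only the 2 genotypes compared, 4 without a filter, 19 with the stricter filter, 22 with an intensity trend, 26 with array weights, 26 at an adjusted p under 0.10 and 3 to 4 with an experiment left out. The 11 genes of Tyk2K923E against WT became 2, 1, 29, 41, 66 and 54 in that order, 20 with median centring, 17 with quantile normalisation and 1 to 6 with an experiment left out. The 3 genes of Tyk2-/- against Tyk2K923E became 2 to 5. Without experiment 1, 2 or 3, the shared calls with the full set were 3, 4 and 3 of 11, then 5, 1 and 1 of 11, and 3, 3 and 2 of 3.

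Lists called went from 11 to 2 with an estimated correlation, 2 with fry and 7 to 14 with leave-outs for Tyk2-/- against WT, and from 9 to 0, 0 and 4 to 9, and to 3 with array weights, for Tyk2-/- against Tyk2K923E. For Tyk2K923E against WT the 10 lists became 7 with an estimated correlation, 7 with fry and 10 to 13 with leave-outs. Signs reversed with array weights for Gzmb (-0.012 between the mutants, -0.020 in Tyk2-/- and -0.0079 in Tyk2K923E), Isg15 (0.043 between the mutants) and Klrg1 (0.024 in Tyk2-/-). With leave-outs the differences spanned 0 for Gzmb (-0.029 to 0.046, -0.036 to 0.072 and -0.036 to 0.051 in the same order), Il12rb2 (-0.14 to 0.033 in Tyk2-/-), Irf7 (-0.031 to 0.19 between the mutants), Isg15 (-0.37 to 0.16 between the mutants) and Klrg1 (-0.23 to 0.019 in Tyk2-/-). The mean of the cell cycle list spanned -0.13 to 0.44 between the mutants and -0.075 to 0.31 in Tyk2-/-. Leaving out experiments 1, 2 or 3 gave Ifi27 an adjusted p of 0.16, 1 and 0.312 in Tyk2-/- against WT and Mapk8 0.127, 1 and 0.894. Wdfy4 lost its call without experiment 1 (0.0674) or 3 (0.343) and Ckap4 without experiment 2 (0.125) or 3 (0.196). In Tyk2K923E against WT, Ifi27 read 0.0534, 1 and 0.195. Between the mutants Ckap4 read 0.061, 0.157 and 0.28, Mapk8 0.0701, 1 and 1, and Wdfy4 0.0701 without experiment 1 and 0.468 without experiment 3. With an experiment left out, 2 arrays per genotype remain.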

Other observations

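The comparison of experiment 1 with experiments 2 and 3 was chosen after the arrays were seen to part, and no explanation was tested. It sets 1 experiment against 2, and the 3 arrays of an experiment are not independent replicates of it, so the p-values and counts describe these arrays only. Cell cycle genes were lower in experiment 1 in 37 of 38 members, with a median log2 difference of -0.73 (camera adjusted p = 2.95e-15, and adjusted p = 0.458 with an estimated correlation), among them the kinetochore genes Cenpe (-1.78) and Cenpf (-1.58) and the replication gene Mcm5 (-0.97). The immediate early genes Egr1 (0.98) and Junb (0.66) and the glycolytic genes Aldoc (0.78) and Pdk1 (0.44) were higher. So were the checkpoint receptor Ctla4 (1.45), the integrin chain Itgam (1.40) and the Fc receptor Fcgr3 (0.84), whereas the chemokine Ccl3 was lower (-1.30).

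In limma, 4623 of 12579 genes had an adjusted p under 0.05, 2045 higher and 2578 lower in experiment 1. The glycolysis, immediate early and checkpoint lists gave camera adjusted p of 0.00258, 0.00622 and 0.0379, and adjusted p = 0.458 each with an estimated correlation. The integrated stress list gave no call (camera adjusted p = 0.563), with 4 members higher, among them Ddit3 (1.32) and Trib3 (0.71), and 5 lower, among them Sdf2l1 (-0.46). Type I interferon-stimulated genes went both ways, with 7 higher and 7 lower (camera adjusted p = 0.949). Each experiment holds 1 array per genotype, so the number of arrays is balanced over the genotypes, but the difference was not of equal size on them. On the first principal component the experiment 1 arrays scored -24.1 in WT, -29.1 in Tyk2K923E and -12.9 in Tyk2-/-. In experiment 1 the mean of the cell cycle list against WT was 0.24 in Tyk2-/- and -0.39 in Tyk2K923E.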
